A study of Mus musculus with 2 samples.

How the data were processed

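The deposited UMI counts of the authors were used as they are: 1 gene by barcode matrix per library, with 32285 genes in each. The submitters' processing notes name Cell Ranger 5.0.0, Seurat 4.1.1 and the mouse build mm10, and the matrix headers name Cell Ranger too. No read was aligned again. The labels put both libraries in a single batch, give 10000 to 13000 loaded cells, and name adipose tissue everywhere except a description field that names embryonic hindlimb; the samples were treated as adipose tissue. The wild-type library holds more barcodes than cells loaded.

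Which library belongs to which genotype, the comparisons, the marker genes of 21 classes, the 25 gene lists (364 genes), the filters and the rule for named genes were fixed before the data were examined. Barcodes with at least 500 UMIs, at least 200 genes and at most 20% mitochondrial UMIs passed, which removed 996 knockout and 223 wild-type barcodes. Doublets were scored with Scrublet (expected rate 0.08). Its automatic threshold called 364 knockout doublets but failed in the wild-type library, where it called 2 of 15332 (0.013%). A fixed score of 0.25, chosen after seeing the data, removed 435 knockout (4.52%) and 478 wild-type barcodes (3.12%).

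Kept cells of both libraries were clustered together, on 2000 variable genes, 30 principal components, a shared neighbour graph with 20 neighbours and Leiden resolution 1.0, with no step to align the libraries. A cluster took the class with the best marker score when at least 3 markers reached 20 CPM and 2-fold over the other clusters and the score was at least 1.0. Another class of the same lineage replaced it when it had more markers among the 10 leading genes and at least 3 at those limits. A cluster stayed unnamed when markers of another lineage reached 0.6 of the score of its class, or when another lineage led its 10 leading genes. It also stayed unnamed when its depth was under 0.333 of the typical depth with no marker among those genes. Lyve1 and Pf4 were not counted as foreign markers of macrophages, a rule chosen after seeing the data. Besides the pair of shallow clusters described in the results, unnamed clusters were cluster 10 (2.51% of knockout and 3.66% of wild-type cells), cluster 11 (7.59% and 0.108%), cluster 18 of cycling cells (0.826% and 2.26%), cluster 22 (1.99% and 0.0471%) and cluster 26 (0.674% and 0.0269%). The 9 classes with at least 100 cells in both libraries were compared. Macrophage-like and monocyte-like cells were clustered again at resolution 0.5.

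UMIs were summed over the cells of a class and library and divided by the class total, as CPM. Intervals are exact Poisson intervals for levels, exact conditional intervals for ratios and Clopper-Pearson intervals for shares. A count of 0 was read as up to 3 counts. Genes entered the counts of differences at a mean of 50 CPM or more and at least 30 UMIs in the higher library; list members needed 10 CPM. Each list median was set against 10000 random lists drawn from 20 bins of expression. Named genes are the 12 highest and 12 lowest ratios in macrophage-like, progenitor-like and T-like cells and 3 of each elsewhere, without ribosomal, mitochondrial, haemoglobin, immunoglobulin and receptor segment genes, predicted Gm genes and Rik clones; list examples are the most abundant member and the one with the largest ratio, and others were picked after their values were seen. For detection each cell was thinned to 2000 UMIs.

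The free RNA profile of each library came from its shallowest unnamed cluster without detected markers and with at least 100 barcodes of that library: cluster 11 in the knockout (698 barcodes, median 865.5 UMIs) and cluster 3 in the wild type (2178 barcodes, median 1418). Its share of a class was the median, over markers of other lineages, of the class level over the profile level. Such markers thus tend to come out near their whole level by construction. A gene counts as mostly from free RNA at 50% or more, and no subtracted value is given above 75%. These free RNA rules were chosen after seeing the data. The knockout estimates are wide, with quartiles of 8.36% and 66.7% in progenitor-like cells, and cluster 11 carries transcripts of sperm as well as of adipose cells.

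The procedure was tested on simulated data, drawn with counting error only around a common profile. There 95% intervals held the true ratio in 95.5% of genes drawn as macrophage-like cells, and every 4-fold difference was recovered (100%). Of true 2-fold differences, which lie on the threshold itself, 41.7% passed it, and 0 of 2302 unchanged genes did. The draws held no difference between animals, in cell mix or in free RNA, so they say nothing about those. A true free RNA share of 20% in T-like cells was estimated at 19.9%. Its profile was known and its markers had been removed from the cells beforehand, so this checks only the computation. Alternatives were other scalings, CPM floors and folds, a stricter cell filter (1000 UMIs, 500 genes, 10% mitochondrial UMIs), no filter, doublets kept, resolutions 0.5 and 2.0, each library clustered alone, cells classed without clusters, and cells thinned to 1000 UMIs. Tests between genotypes, trajectories, ligand and receptor scores and the raw reads were left out. Tools were Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9; TMM was computed in Python and gave the factors of edgeR 4.0.16 under R 4.3.3.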

Results

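Single-cell 3' RNA-seq was analysed from the stromal vascular fraction of epididymal white adipose tissue, the cells left when mature adipocytes are removed from digested fat, after 10 weeks of high-fat diet. 1 library came from a conditional knockout of Camk2d in myeloid cells (knockout) and 1 from the wild type. The knockout library held 10631 barcodes and 87015920 UMIs, with a median of 7385 UMIs and 2222 genes per barcode. The wild-type library held 15555 barcodes and 75436672 UMIs, with a median of 3094 UMIs and 1276 genes. After filtering, 9200 knockout and 14854 wild-type barcodes were kept, with medians of 8257 and 3122.5 UMIs. They fell into 30 clusters, of which 23 took a cell class from marker genes. With 1 library per genotype no difference between genotypes was tested. Intervals are 95% and cover counting error only, not the spread between animals.

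The labels were compared with transcripts of known sex and tissue. Xist, transcribed from the inactive X of females, had 6 UMIs in the knockout and 2 in the wild-type library, and the Y-linked Ddx3y had 8505 and 6066, the pattern of male mice in both. A label field of both samples names embryonic hindlimb, against adipose tissue in the other fields. Transcripts of limb muscle, cartilage and patterning (Myf5, Myog, Pax7, Acan, Hoxd13) and the embryonic globins Hbb-y and Hba-x had 0 UMIs in both libraries, which allows up to 0.0345 CPM (a gene's UMIs scaled to a fixed total) in the knockout and 0.0398 CPM in the wild type. Myod1 had 1 and 7 UMIs, Myh3 4 and 11, Acta1 10 and 2 and Col2a1 6 and 1, and Sox9, which is transcribed outside cartilage too, had 2942 and 1527.

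The level of Camk2d, the targeted gene, was compared in each class to see where the libraries differed in it. Camk2d (ENSMUSG00000053819, plus strand of mm10 chromosome 3, 126596302 to 126846326) encodes the delta chain of calcium/calmodulin-dependent protein kinase II. In macrophage-like cells it was lower in the knockout library, at 26.03 CPM (23.4 to 28.8, 370 UMIs) against 45.1 CPM (42.0 to 48.3, 816 UMIs), a log2 ratio of knockout over wild type of -0.79 (-0.97 to -0.61). It was also lower in conventional dendritic-like cells, which held 19.3 CPM (14.1 to 25.7) against 34.0 CPM (26.5 to 42.9), a log2 ratio of -0.82 (-1.39 to -0.26). In monocyte-like cells both libraries held 35.9 CPM (30.5 to 42.0 and 28.7 to 44.4; log2 ratio interval -0.39 to 0.40). Outside the myeloid classes, Camk2d was at 174 CPM against 173 CPM in B-like cells (log2 0.01, -0.16 to 0.18), 58.3 against 55.1 in T-like cells (log2 0.08, -0.17 to 0.34) and 91.2 against 99.4 in progenitor-like cells (log2 -0.12, -0.20 to -0.05). Natural killer-like cells held 41.2 against 46.1 CPM (log2 -0.16, -0.69 to 0.37) and blood endothelial-like cells 43.6 against 49.5 CPM (log2 -0.18, -0.65 to 0.29). Erythroid-like cells held 5.33 CPM (3 UMIs) against 28.7 CPM (log2 -2.43, -4.74 to -0.81). That direction reverses with equal weight per cluster, and all genes of this class centred at -1.45 under TMM scaling.

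The other kinase chains were near level in macrophage-like cells. Camk2g held 15.3 CPM against 14.1 CPM (log2 0.12), Camk2a 5.21 against 6.63 (-0.35) and Camk2b 1.27 against 1.44 (-0.18). Lyz2, a gene of myeloid cells, was at 7745 CPM against 6805 CPM in macrophage-like cells (0.19) and 7454 against 6913 in monocyte-like cells (0.11). Free RNA, transcripts from other cells caught in a droplet, made up an estimated 6.68% of UMIs in knockout and 17.0% in wild-type macrophage-like cells, and 43.9% of the wild-type Camk2d level in dendritic-like cells. The labels give neither the deleted exons nor the Cre driver, and 3' tags can lie outside the deleted part, so these levels check nothing about the deletion itself.

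Camk2d was next counted cell by cell, with every cell thinned to 2000 UMIs to even out depth. It was detected in 6.14% of knockout and 8.61% of wild-type macrophage-like cells, and without thinning in 23.6% and 29.4% (median depth 11977 and 7649 UMIs, 64 and 26 cells under 2000 UMIs left out of the thinned share). Thinned shares were 8.57% and 5.88% in monocyte-like, 27.2% and 28.7% in B-like, 10.5% and 8.71% in T-like and 15.9% and 18.1% in progenitor-like cells. They were 3.41% and 7.75% in conventional dendritic-like, 5.19% and 8.97% in natural killer-like and 8.70% and 11.2% in blood endothelial-like cells, from few cells. The intervals of the thinned shares overlap between the libraries in all of these classes, macrophage-like cells (4.73 to 7.82 and 7.39 to 9.95) included. In erythroid-like cells, a type with little reason to carry the gene, it was seen in 0 of 98 knockout cells after thinning, which allows a share of cells with a UMI of up to 3.06%, and in 20 of 465 wild-type cells (4.30%). Unthinned, the erythroid-like shares were 1.49% and 6.05% (median depth 1775.5 and 1924 UMIs). Free RNA was an estimated 11.5% of knockout and 52.6% of wild-type UMIs in this class, and 104% of its wild-type Camk2d level. The estimated background was thus larger in the wild type. The knockout shares rest on few cells (3 with a UMI, unthinned), and the direction of the level reverses with equal weight per cluster.

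**Figure D1:**
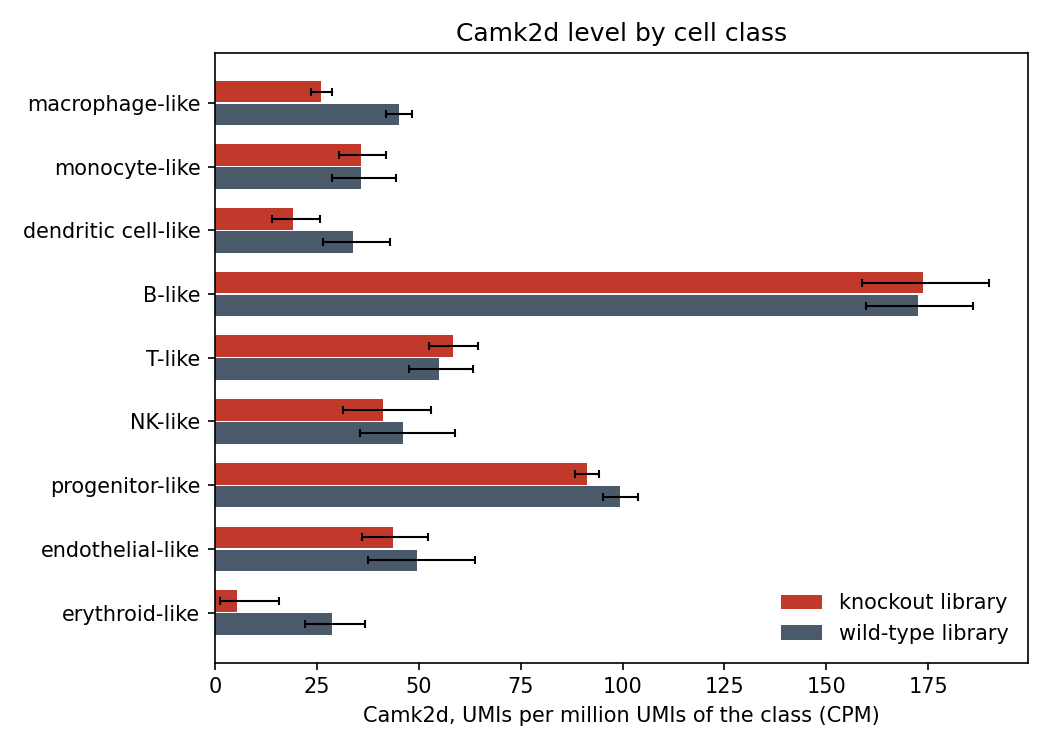
Camk2d level by cell class in the knockout and wild-type libraries, in CPM on a linear axis. Bars are levels and error bars are 95% Poisson intervals of the UMI count. In macrophage-like cells the levels were 26.03 and 45.1 CPM.

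The cell make-up of the fraction was compared by the share of kept cells in each class. Fibroblast and adipose progenitor-like cells made up 41.6% of the knockout library (40.6 to 42.6) and 19.2% of the wild-type library (18.6 to 19.9), and T-like cells 11.8% (11.2 to 12.5) and 5.75% (5.38 to 6.14). Macrophage-like cells had closer shares, 11.5% (10.8 to 12.2) and 13.1% (12.5 to 13.6). Monocyte-like cells made up 3.50% and 2.40%, B-like 4.42% and 4.78%, natural killer-like 2.58% and 2.21%, conventional dendritic-like 2.10% and 2.17%, and blood endothelial-like cells 3.84% and 1.33%. Erythroid-like cells were at 2.20% against 6.90%, but at 8.33% against 6.74% with every deposited barcode and 0.0891% against 6.57% with the stricter filter. A cluster like group 2 innate lymphoid cells (ILC2), which also carried the T-cell receptor transcript Trbc1, was at 0.848% against 2.54%. The log2 ratios were 1.11 for progenitor-like, 1.04 for T-like and -0.19 for macrophage-like cells.

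These shares rest on unlike barcodes. The lowest barcode held 500 UMIs in the knockout and 1276 in the wild-type library, and clusters without a class held 14.3% of knockout and 38.9% of wild-type cells. Of the wild-type cells, 32.8% lay in a pair of shallow clusters with transcripts of several lineages, which held 0.728% of knockout cells. Over named cells without erythroid-like cells the shares were 13.8% and 24.1% for macrophage-like, 49.8% and 35.5% for progenitor-like and 14.2% and 10.6% for T-like cells, and T-like and ILC2-like cells together came to 15.2% and 15.3%. With each library clustered alone no cluster was named monocyte-like, and the macrophage-like shares of 20.4% and 13.2% stand beside 14.99% and 15.5% for macrophage-like and monocyte-like cells together in the joint clustering; 414 wild-type cells were then named neutrophil-like. The blood endothelial-like shares in that setting were 1.59% and 1.25%, or 2.20% and 1.51% with each cell classed alone. Single clusters were also lopsided: progenitor-like cluster 0 held 2591 knockout and 198 wild-type cells against 667 and 1689 in cluster 2, and T-like cluster 15, with Cd4 among its leading genes, held 489 and 6. A cluster found almost only in 1 library can be a trait of that library and not a cell type.

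**Figure D2:**
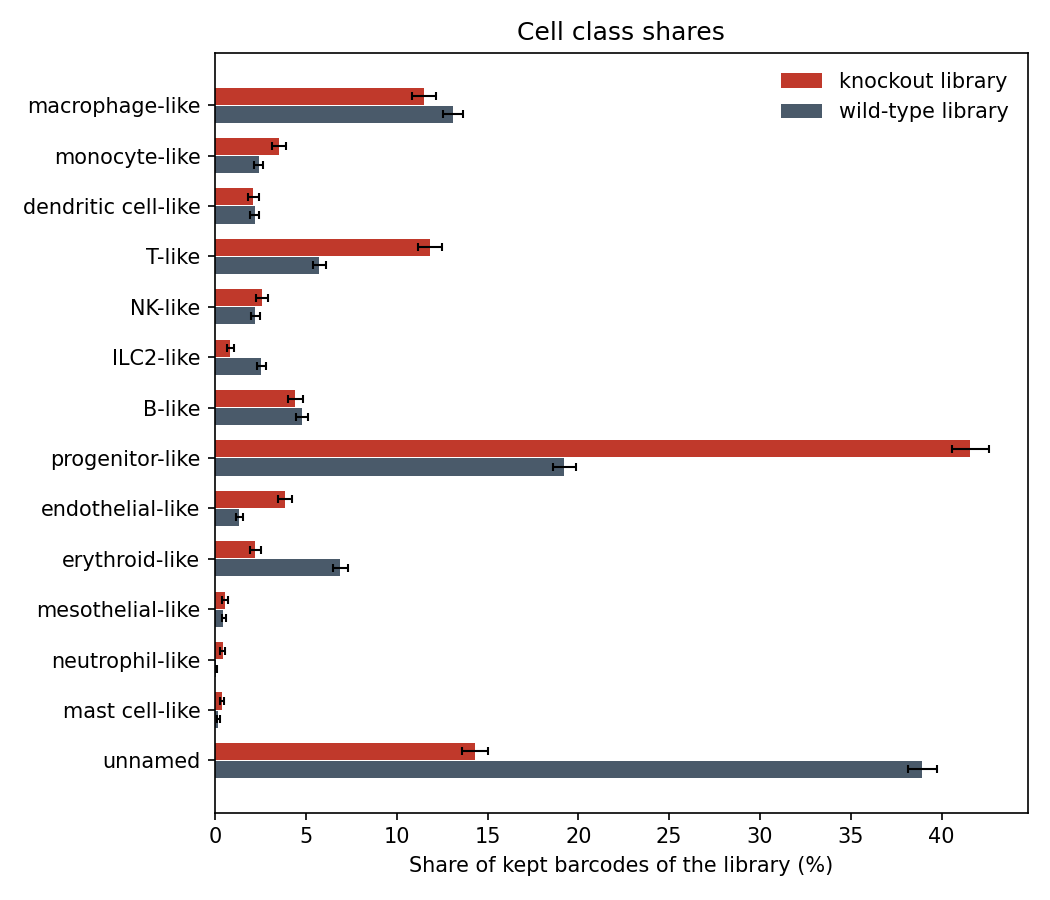
Share of kept cells in each class in the knockout and wild-type libraries, in percent. Bars are shares and error bars are 95% Clopper-Pearson intervals. Progenitor-like cells made up 41.6% and 19.2%, and cells without a class 14.3% and 38.9%.

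Gene levels of macrophage-like cells, the cells the knockout was aimed at, were compared through summed UMIs of 1057 knockout and 1943 wild-type cells. Chemokines that draw monocytes were higher in the knockout library: Ccl12 at 160 CPM against 21.1 CPM (log2 2.93, 2.77 to 3.09), Ccl7 at 1208 against 323 (1.90) and Ccl2 at 1692 against 482 (1.81). So were the adhesion molecule Vcam1 (112 against 27.5 CPM, 2.03), the alternative-activation product Retnla (6343 against 1679 CPM, 1.92, 1.90 to 1.94) and the haemoglobin scavenger receptor Cd163 (163 against 48.0 CPM, 1.76). Lower in the knockout library were the lysosomal protease Ctsk (92.5 against 429 CPM, -2.21, -2.30 to -2.13), Mfge8, which bridges dying cells to phagocytes (94.99 against 307 CPM, -1.69), and Gpnmb and Lgals3, genes of lipid-laden macrophages (558 against 1377 CPM, -1.30, and 3141 against 6436 CPM).

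Further genes on the higher side were Egr3 (108 against 32.9 CPM, 1.72) and Rcan1 (283 against 90.1 CPM, 1.65), targets of calcium signalling through calcineurin and NFAT, with Bmp2 (1.58), Marcksl1 (435 against 154 CPM), Ccl24 (350 against 128 CPM, 1.45) and Ccl4 (449 against 166 CPM, 1.44). On the lower side were Pcdh7 (-1.43), Zranb3 (-1.41), Syngr1 (-1.37), the creatine kinase Ckb (201 against 478 CPM, -1.25), Stmn1 (-1.24) and Wfs1 (-1.10). Col3a1 (-1.57) and Col1a2 (-1.16) were also among the 12 lowest, and for these the free RNA estimated for the wild-type library was 112% and 109% of the measured level. Both are markers that help set that estimate, so values near the whole level are partly built in. Of 2514 genes at 50 CPM or more, 32 were at least 2-fold higher and 13 at least 2-fold lower, 2 of the lower mostly from free RNA. Median-of-ratios scaling gave 45 higher and 10 lower, and the mean of per-cell CPM gave 18 and 17. The class joined cluster 5 (640 knockout and 828 wild-type cells, with Ccl12, Ccl4 and Retnla among its leading genes), cluster 7 (244 and 836, with Gpnmb, Lgals3 and Mmp12) and cluster 17 (173 and 279). With equal weight per cluster the log2 ratios were 1.95 for Ccl12, 1.47 for Retnla, 1.15 for Ccl7, 1.16 for Ccl2, 1.05 for Cd163, 0.76 for Bmp2, 0.90 for Ccl24, 0.69 for Ccl4, -1.69 for Ctsk, -1.10 for Mfge8, -0.93 for Pcdh7, -0.74 for Zranb3, -0.60 for Gpnmb, -0.45 for Wfs1 and -0.52 for Lgals3.

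Gene lists asked which programs of macrophage-like cells went with these genes. Of 18 measured inflammatory genes 13 were at least 1.5-fold higher in the knockout library, 0 lower and 5 between, among them Il1b (831 against 310 CPM, 1.42) and Cxcl2 (7192 against 4691 CPM, 0.62). The list median was 0.79, above the -0.26 to 0.10 that held 95% of 10000 random lists matched for expression. Interferon response genes had 6 higher, 0 lower and 6 between (median 0.60; random lists -0.29 to 0.11), with Ifi204 at 173 against 93.6 CPM (0.88) and Bst2 at 139 against 108 CPM (0.36). Genes of resident macrophages had 6 higher, 0 lower and 7 between (median 0.53; -0.30 to 0.15), with Lyve1 at 281 against 134 CPM (1.06) and Selenop at 4364 against 3881 CPM (0.17). Alternative-activation genes had 4 higher, 0 lower and 7 between (median 0.53; -0.31 to 0.18), with Klf4 at 1306 against 834 CPM (0.65). MHC class II genes had 1 higher, 0 lower and 7 between (median 0.50; -0.33 to 0.22), with H2-Eb1 at 3581 against 2358 CPM (0.60) and Cd74 at 8366 against 5738 CPM (0.54).

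Genes of lipid-associated macrophages went the other way: 0 of 18 were higher, 9 lower and 9 between (median -0.60; random lists -0.28 to 0.10). Mmp12 was at 418 against 780 CPM (-0.90), while Apoe was near level (12433 against 11770 CPM, 0.08). The lists of glycolysis and oxidative phosphorylation had medians below their random ranges, most of their members being between. Glycolysis was at -0.48 (0 higher, 5 lower, 8 between; Gapdh 525 against 828 CPM, -0.66) and oxidative phosphorylation at -0.43 (0 higher, 2 lower, 15 between; Cox4i1 562 against 854 CPM, -0.60). Immediate early genes, which also mark handling of the tissue, had 3 higher, 0 lower and 14 between (median 0.14, random lists -0.28 to 0.10), with Zfp36 at 1634 against 834 CPM (0.97). With equal weight per cluster that median was -0.19, inside its random range. Medians for lysosome (-0.17), cholesterol (0.01), fatty acid oxidation (-0.06), calcium handling (0.03) and the calmodulin kinases (0.02) lay inside their random ranges. With equal weight per cluster the medians were 0.68 for the inflammatory, 0.39 for the interferon, 0.05 for the resident, 0.18 for the alternative-activation and -0.19 for the lipid-associated list, so the resident and lipid-associated medians were then inside the random ranges above and the alternative-activation median at the edge of its own. Equal weight per cluster does not balance the subclusters described below. Within those compared, the inflammatory medians were lower, from -0.33 to 0.41.

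**Figure D3:**
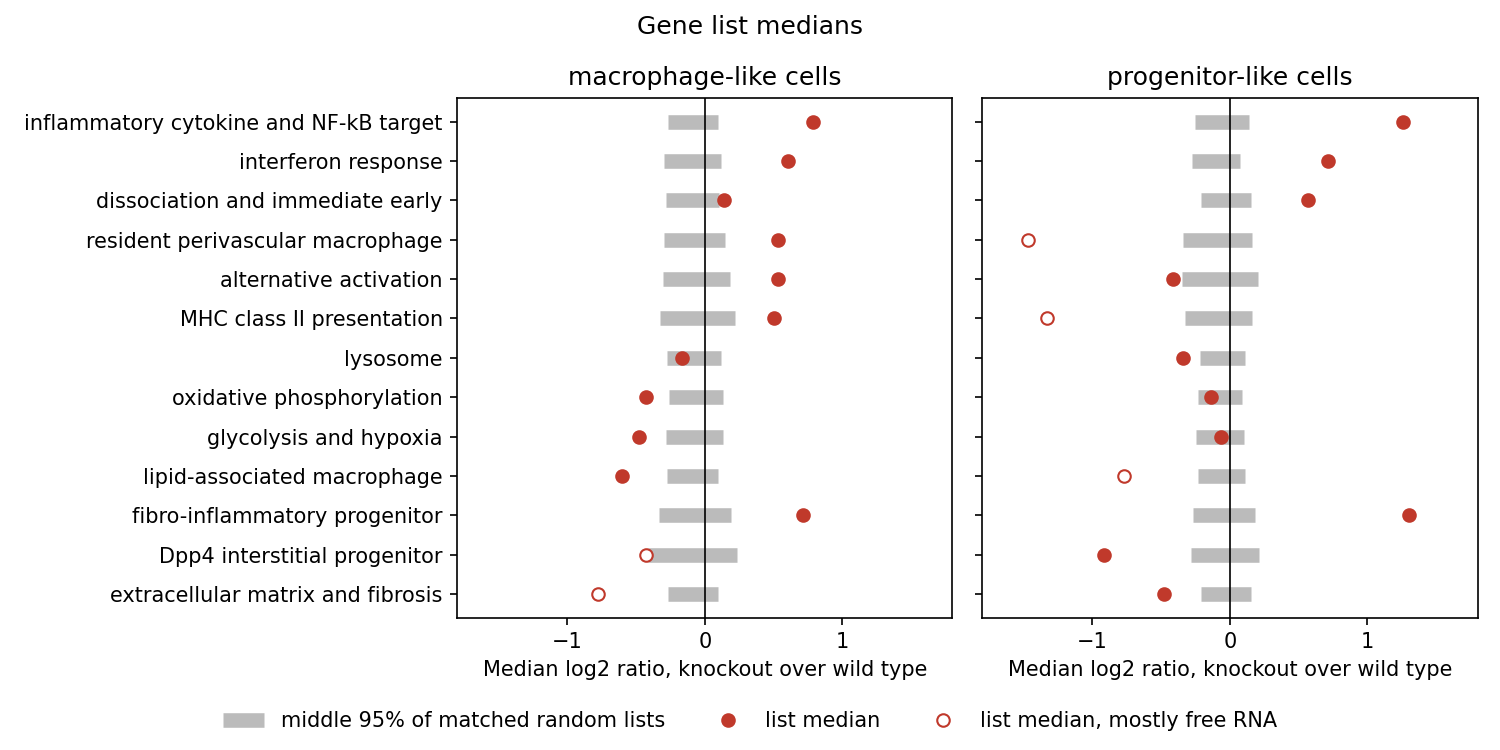
Median log2 ratio of knockout over wild type for each gene list in macrophage-like (left) and progenitor-like cells (right); grey bars span the middle 95% of 10000 matched random lists and open points are lists mostly from free RNA. In macrophage-like cells the inflammatory median was 0.79 and the lipid-associated median -0.60.

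Subclusters of the 1379 knockout and 2299 wild-type macrophage-like and monocyte-like cells asked whether the programs were spread over all of these cells or lay in a few kinds. The lipid-associated subcluster 0 held 7.25% of knockout and 27.2% of wild-type cells, and subcluster 4, with the highest score for the resident list (2.44), held 6.82% and 16.3%. Clustered without the genes of the lipid-associated and resident lists, the shares were 6.16% and 26.2% for the lipid-associated and 6.45% and 16.01% for the highest resident kind. Subcluster 5, with a resident score of 1.35, was 371 knockout and 29 wild-type cells (26.9% and 1.26%), and subcluster 1, with a score of 1.22, held 14.9% and 16.9%, so resident genes marked subclusters of either direction. Subcluster 5 also had the highest score for the inflammatory list (0.86), and its wild-type cells were too few for gene ratios. At resolution 0.25, where subclusters are wider, the highest resident kind held 39.8% of knockout and 34.7% of wild-type cells, the other direction.

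Within subclusters the interferon list was higher in the knockout library in each of the 6 kinds with enough cells in both libraries, with medians of 0.56, 0.54, 0.43, 0.65, 0.29 and 0.68 for subclusters 0, 1, 2, 3, 4 and 6. The inflammatory list was not: its medians were 0.03, -0.33, -0.13, 0.41, 0.38 and 0.17. The lipid-associated list ran from 0.28 in subcluster 0 to -1.34 in subcluster 6, and the resident list from -1.70 in subcluster 6 to 0.88 in subcluster 1. None of these ratios was corrected for free RNA. Extracellular matrix genes had medians from -1.39 in subcluster 0 to -2.24 in subcluster 6, so wild-type free RNA can lower medians here. Subcluster 6 had the lowest scores for the lipid-associated and resident lists (-1.81 and -1.82), so its low medians may be background. Camk2d was lower in the knockout library in 6 of the 6 subclusters with at least 50 cells in both libraries. The log2 ratios ran from -0.31 to -0.85, and the whole interval was below 0 in 3 subclusters (0, 3 and 4). Subclusters 5, 7, 8 and 9 held too few cells. Among these was subcluster 7 (61 and 45 cells), which had the highest monocyte marker score (3.51).

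**Figure D4:**
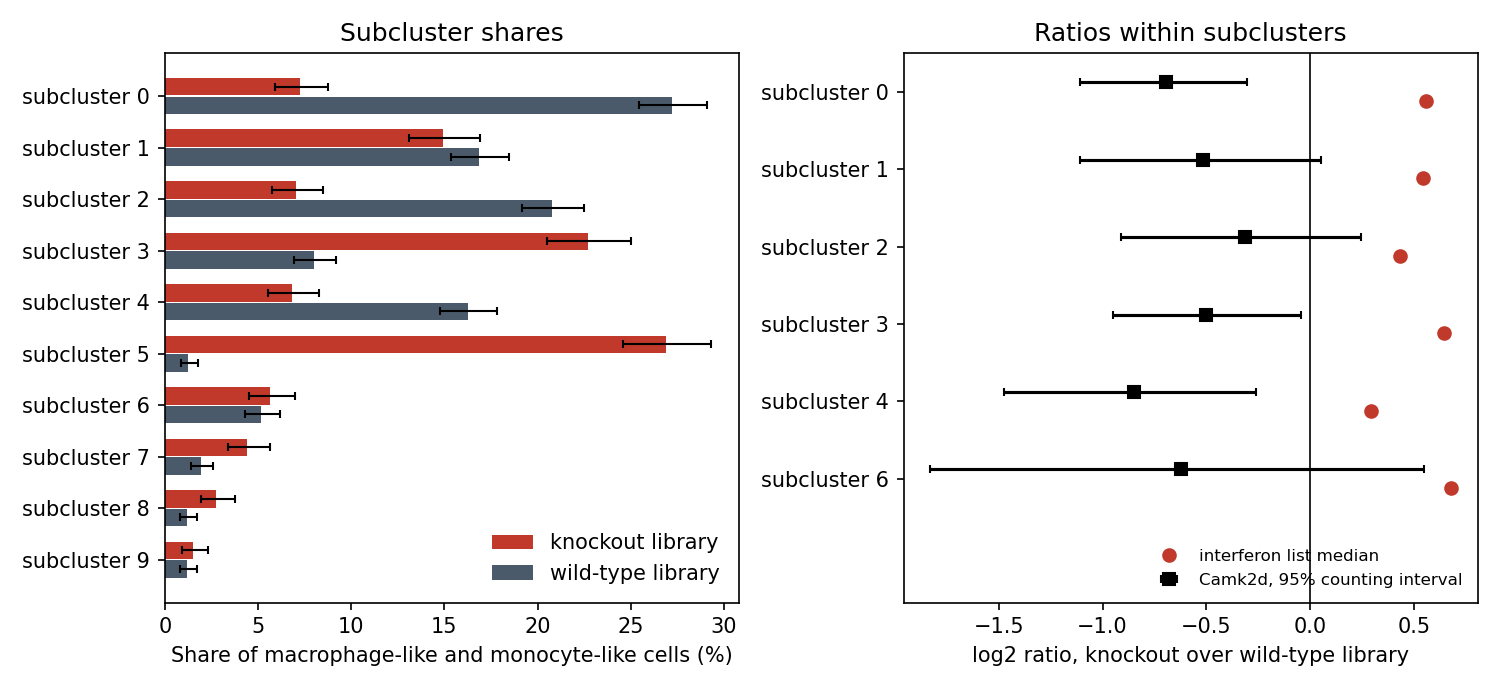
Left, share of macrophage-like and monocyte-like cells in each subcluster of both libraries, in percent with 95% Clopper-Pearson intervals. Right, log2 ratio of Camk2d (with 95% counting interval) and median log2 ratio of the interferon list in each subcluster, -0.70 and 0.56 in subcluster 0.

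Progenitor-like cells, which lie outside the targeted lineage, were compared to see whether the libraries also differed beyond myeloid cells. Secreted inflammatory genes were higher in the knockout library: the pentraxin Ptx3 at 474 against 96.1 CPM (log2 2.30, 2.24 to 2.37), the neutrophil chemokine Cxcl1 at 1633 against 351 CPM (2.22, 2.18 to 2.25), the cytokine Il6 at 295 against 74.5 CPM (1.99) and Ccl7 at 701 against 232 CPM (1.59). The interferon-induced GTPase Iigp1 was at 129 against 26.7 CPM (2.27) and the transcription factor Irf1 at 272 against 84.6 CPM (1.69). Adm (1.86), Myc (317 against 102 CPM, 1.64), Smpd3 (149 against 51.4 CPM, 1.54), Zfp36 (3105 against 1083 CPM, 1.52), Ifi205 (1003 against 364 CPM, 1.46) and Nop58 (1.42) were higher too. Thy1, a surface protein of fibroblasts (25.1 against 96.0 CPM, -1.93), and Sfrp4, a Wnt inhibitor (30.6 against 111 CPM, -1.86), were lower.

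The other 10 of the 12 lowest genes (Lgals3, Lcp1, S100a4, Cd52, Tyrobp, Ccl9, Ucp2, C1qb, Ccl6 and Fabp5) are genes of immune cells, and free RNA made up an estimated 82.7% to 123% of their wild-type level. C1qb is itself a marker that helps set this estimate. Of 2566 genes 42 were at least 2-fold higher and 44 at least 2-fold lower, 21 of the lower mostly from free RNA. TMM scaling gave 59 and 33, median-of-ratios scaling 60 and 33, and equal weight per cluster 5 and 24. Cluster 0 held most knockout cells (2591 against 198) and cluster 2 most wild-type cells (667 against 1689), and Ptx3, Ifi205, Myc, Il6 and Adm are among the leading genes of cluster 0. With equal weight per cluster the log2 ratios were 0.88 for Ptx3, 1.39 for Cxcl1, 0.77 for Il6, 1.59 for Iigp1, 1.03 for Adm, 0.81 for Irf1, 0.77 for Myc, 0.56 for Ccl7, 0.96 for Zfp36, 0.72 for Ifi205, 0.46 for Nop58, 1.81 for Smpd3, -0.99 for Thy1 and -0.86 for Sfrp4.

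Lists in progenitor-like cells placed these genes in programs. The inflammatory list had 8 higher, 2 lower and 2 between (median 1.26; random lists -0.26 to 0.14) and the fibro-inflammatory progenitor list 7 higher, 1 lower and 3 between, with Ccl2 at 1.40 and C3 at 0.35 (4143 against 3253 CPM). Interferon response genes had 7 higher, 0 lower and 6 between (median 0.71; -0.28 to 0.07), with Gbp2 at 94.4 against 39.0 CPM (1.28) and Ifi204 at 480 against 276 CPM (0.80). Immediate early genes had 8 higher, 0 lower and 9 between (median 0.57, random lists -0.21 to 0.15), with Fos at 5158 against 3345 CPM (0.62). These genes also mark handling of the tissue, which was not tested as a source of the higher inflammatory genes. Genes of Dpp4-positive progenitors had 0 higher, 5 lower and 3 between (median -0.91; -0.28 to 0.21), with Cd55 at 258 against 646 CPM (-1.33) and Pi16 at 313 against 724 CPM (-1.21). Extracellular matrix genes had 2 higher, 5 lower and 11 between (median -0.48; -0.21 to 0.15), with Fbn1 at 911 against 1942 CPM (-1.09) and Thbs1 at 432 against 190 CPM (1.18). Adipogenic genes were divided, 3 higher, 3 lower and 3 between (median 0.24). Equal weight per cluster gave 0.51 for the inflammatory, 0.66 for the fibro-inflammatory, 0.47 for the interferon, 0.33 for the immediate early and -0.27 for the extracellular matrix list, and -0.18 for the Dpp4 list, inside its random range.

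T-like cells were compared to see which lymphocyte genes differed. The ILC2-like cluster (78 knockout and 377 wild-type cells), which also carried Trbc1, is not part of this class. Any T cells in that cluster are therefore not counted here. Some genes of helper and regulatory cells were among those with the highest ratios of knockout over wild type. Cd4 was at 106 against 6.88 CPM (log2 3.94, 3.36 to 4.597). The costimulatory receptor Tnfrsf4 was at 114 against 14.6 CPM (2.97) and the inhibitory receptor Ctla4 at 162 against 40.1 CPM (2.01). The granule protease Gzma was at 109 against 4.87 CPM (4.48, 3.79 to 5.27; 17 UMIs in the wild type). Ly6a (359 against 104 CPM, 1.79), Cd5 (143 against 49.0 CPM, 1.55), Inpp4b (1.60), Slfn1 (1.51) and the histone genes Hist1h2ae (1.77), Hist1h2ap (1.77), Hist1h1b and Hist1h4d (1.55) were also higher. Among the lowest genes, Lum, Mgp, Col3a1, Fstl1, Gpnmb, Col1a1, Trem2, Lgmn, Lgals3, Col1a2 and Fbn1 (log2 -2.80 to -2.53) are genes of macrophages and stroma, and free RNA made up an estimated 90.8% to 110% of their wild-type level. Lum, Col3a1, Col1a1 and Col1a2 are themselves markers that help set this estimate.

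Of 2380 genes 41 were at least 2-fold higher and 98 at least 2-fold lower, 91 of the lower mostly from free RNA; equal weight per cluster gave 7 and 94. The class joined cluster 15 (489 knockout and 6 wild-type cells, with Cd4 among its leading genes), cluster 8 (473 and 583, with Cd8b1), cluster 20 (79 and 248, with Trdc) and the cycling cluster 27 (47 and 17), which Hist1h genes lead. Equal weight per cluster takes only clusters with at least 50 cells in both libraries, here clusters 8 and 20, and so leaves out the Cd4 and the cycling cluster. It gave 2.24 for Cd4, 1.81 for Tnfrsf4, 1.43 for Ctla4, 0.73 for Gzma, 0.98 for Hist1h4d, -0.06 for Hist1h2ae and -1.18 for Hist1h1b. The list of T cell effector and exhaustion genes had 4 higher, 0 lower and 8 between (median 0.44, random lists -0.08 to 0.31). Ifng was at 102 against 46.5 CPM (1.13) and Ccl5 at 8347 against 5686 CPM (0.55). The median of this list was 0.14 after subtraction of free RNA. The list of regulatory T and type 2 cell genes had 5 higher, 1 lower and 2 between (median 0.63, random lists -0.24 to 0.30). Tnfrsf18 was at 152 against 99.8 CPM (0.61), and the list median was 0.31 after the same subtraction. Interferon response genes had 5 higher, 1 lower and 4 between (median 0.44; -0.30 to 0.29), with Bst2 at 86.2 against 54.8 CPM (0.65); equal weight per cluster gave 0.17, inside that range. Proliferation genes had 11 higher, 0 lower and 3 between (median 0.83; -0.13 to 0.26), with Mki67 at 150 against 70.5 CPM (1.09), but a median of -0.46 with equal weight per cluster, without the cycling cluster.

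Classes were then set side by side to see which differences they shared. The interferon list median was above its random range in monocyte-like (0.58; 5 higher, 0 lower, 6 between), natural killer-like (0.65), B-like (0.53) and blood endothelial-like cells (0.77; 9 higher, 0 lower, 5 between) as well as in macrophage-like, progenitor-like and T-like cells. In blood endothelial-like cells myeloid genes were higher too, with a MHC class II median of 1.49, a resident macrophage median of 0.82 and Lyz2 at 1.48, and subtraction of free RNA left an interferon median of 0.37. In conventional dendritic-like cells it was 0.12, inside the range of -0.38 to 0.24. Across 1740 genes the log2 ratios of progenitor-like and macrophage-like cells had a Pearson correlation of 0.491 (Spearman 0.549), and 0.593 over the 1493 genes with little free RNA. T-like cells had 0.317 with progenitor-like cells (1543 genes) and 0.0858 with macrophage-like cells (1711 genes), or 0.297 (900 genes) and 0.279 (1119 genes) with little free RNA. T-like cells were closer to natural killer-like (0.815), B-like (0.709) and conventional dendritic-like cells (0.639), or 0.447, 0.355 and 0.383 with little free RNA. With monocyte-like cells the value was 0.222, but 0.394 with little free RNA, above the B-like and dendritic-like values. These coefficients run across genes within a single pair of libraries, so they carry no information on animals, and free RNA shared by classes enters them.

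Scaling moved all genes of a class together. TMM and median-of-ratios scaling placed the centre of the genes, on the scale of total UMIs, at -0.10 and -0.12 in macrophage-like, -0.16 and -0.17 in progenitor-like, -0.11 and -0.13 in monocyte-like and -0.11 and -0.12 in blood endothelial-like cells, so every log2 ratio was higher by as much under those scalings. In erythroid-like cells the centres were -1.45 and -1.49, and gene ratios of that class other than Camk2d are left out.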

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

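These results are signals in data that the comparisons of the report do not describe, and were picked out for that reason. Sperm transcripts appeared in the knockout library: Prm2, which packs sperm chromatin, had 3065 UMIs in 86 barcodes (35.2 CPM) against 0 in the wild type, which allows up to 0.0398 CPM; Smcp had 517 against 0 and Prm1 466 against 1. Of the Prm2 UMIs, 1711 were in barcodes of the erythroid-like class. An unnamed cluster led by Prg4, Serpinb2 and Alox15, genes of resident cavity macrophages, held 62 knockout and 4 wild-type cells. In the wild-type library 4878 barcodes lay in the shallow unnamed clusters 1 and 3, which mix transcripts of several lineages, against 67 in the knockout. The mast cell genes Mcpt4, Cma1 and Tpsb2 were among the leading genes of both clusters. Mast cell-like cells numbered 34 knockout and 27 wild-type in the joint clustering, and 81 and 626 with each cell classed alone. The 2178 barcodes of cluster 3 also gave the wild-type free RNA profile.

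For the lower Camk2d of macrophage-like cells, all 3 tests were chosen after the result was seen. Free RNA from other cells was weighed by subtracting it, which left a log2 ratio of -0.74 (-0.95 to -0.54), so it does not account for the difference. Another mix of macrophage subclusters was weighed with equal weight for each of the 6 subclusters with at least 50 cells in both libraries. That left -0.58 (-0.81 to -0.35), over macrophage-like and monocyte-like cells together. Subcluster 5 (371 and 29 cells) and the smaller subclusters 7, 8 and 9 could not enter, so their part in the mix was not weighed. A difference of the whole library would lower Camk2d in other classes as well, and the lowest ratio among progenitor-like, T-like and B-like cells was -0.12. Natural killer-like (-0.16, -0.69 to 0.37) and blood endothelial-like cells (-0.18, -0.65 to 0.29) held too few UMIs to tell. Erythroid-like cells were lower beyond counting error. They cannot decide, with 3 knockout cells holding a UMI and all genes of the class centred at -1.45 under TMM scaling. Monocyte-like cells, also myeloid, did not show the difference. Their Camk2d level was the same in both libraries, and their thinned shares were 8.57% in the knockout and 5.88% in the wild type, with overlapping intervals. The genotype could explain what remains in macrophage-like cells, a hypothesis left untested with 1 library of each.

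For the interferon response genes, the tests on free RNA and on the animal were written down before they were run, and the test on handling was chosen after the result was seen. Free RNA from other cells was weighed by subtracting it, and 4 of 4 classes stayed above their random range. The medians were 0.58 in macrophage-like, 0.50 in monocyte-like, 0.76 in progenitor-like and 0.77 in T-like cells. The knockout profile, from cluster 11, carries sperm transcripts. Quartiles of its share were wide, 4.50% and 22.6% in T-like and 8.36% and 66.7% in progenitor-like cells. That spread was not carried into the medians, so free RNA of the knockout library is not excluded. The mix of clusters within a class was not among these tests. With equal weight per cluster the T-like median was 0.17, inside its random range, while the macrophage-like and progenitor-like medians stayed above theirs. Dissociation and handling would raise immediate early genes along with them. These were above their range in 2 of 4 classes (0.14 in macrophage-like and 0.57 in progenitor-like cells, 0.06 in monocyte-like and -0.43 in T-like cells). Unlike the interferon medians here, these were not corrected for free RNA, and the T-like one was -0.06 after subtraction. With equal weight per cluster the macrophage-like median reversed. Handling that raises these genes thus does not account for all 4 classes. It stays open for macrophage-like and progenitor-like cells. The state of the animal apart from its genotype, an infection for example, might give the same pattern and cannot be told apart with 1 library per genotype.

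For the mixed wild-type barcodes, the test on free RNA was written down before it was run, and the test on doublets was chosen after the result was seen. Free RNA without a cell would leave only sampling variance between barcodes, and the median ratio of variance to sampling variance was 1.53 in cluster 1 and 1.10 in cluster 3, against 5.31 in macrophage-like, 5.10 in progenitor-like, 2.01 in B-like and 1.77 in T-like cells. The limits set were 1.5 for free RNA and 3 for cells. By the rule, which took the higher value, 1.53, the test leaves this open. Cluster 3 (1.10) was inside the free RNA limit, and cluster 1 was just outside it. T-like and B-like cells did not reach the limit for cells, so that limit cannot tell lymphocytes from free RNA. Doublets would be deep, and the barcodes had 0.293 of the median depth of named cells (1755 against 5995 UMIs), which speaks against them.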

How the results depend on the processing

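Alternatives chosen after seeing the data were free RNA subtracted, equal weight per cluster, macrophage-like cells without the cluster led by Cd209f and Lyve1, a shared UMI minimum, shares of named cells without erythroid-like cells, T-like and ILC2-like cells joined, subclusters without list genes, genes with little free RNA, and, for genes, lists and Camk2d, the other clusterings, cells classed alone and every barcode. No paired analysis was possible because each genotype has 1 library. Unless said otherwise the cause was not tested. Values are log2 ratios of knockout over wild type.

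The T-like share (1.04) was 0.86 of immune cells, 0.42 of named cells, 0.77 at resolution 0.5, 0.50 with each library clustered alone (0 wild-type cells were then named ILC2-like), 0.89 with every barcode, 1.26 with the shared UMI minimum and 0.77 with cells thinned. The progenitor-like share (1.11) was 0.49 of named cells, 0.99 with libraries alone, 1.01 with each cell classed alone, 1.30 with the strict filter, 0.91 with every barcode, 1.30 with the shared minimum and 1.27 thinned. The macrophage-like share (-0.19) was -0.37 of immune cells, -0.81 of named cells, -0.35 with each cell classed alone, -0.059 with the strict filter and -0.33 with every barcode, and it reversed to 0.0039 with the shared minimum and 0.62 with libraries alone. In that last setting no cluster was named monocyte-like, so its macrophage-like values, here and for Camk2d and the lists, are of another class, and the main share of macrophage-like and monocyte-like cells together was at -0.046. Among other classes with at least 100 cells in both libraries and a main interval clear of 0, reversed shares were the erythroid-like at 0.31 with every barcode (main -1.65), the monocyte-like at -0.078 of named cells (0.55), and T-like and ILC2-like joined at -0.011 of named cells (0.61). With main intervals that include 0, the B-like share (-0.11) was 0.27 with doublets kept, where a plasma-like class of 45 and 265 cells split off, and -0.74 of named cells; with libraries alone 0 knockout cells were named B-like and 404 plasma-like. The natural killer-like share (0.22) was -0.40 of named cells. The blood endothelial-like share (1.53) was 0.35 with libraries alone and 0.54 with each cell classed alone. A smaller denominator moves shares by its construction.

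Camk2d in macrophage-like cells (-0.79) was -0.57 with libraries alone and moved no further than counting error in the other 9 alternatives. In erythroid-like cells (-2.43, 3 knockout UMIs) it reversed to 0.47 with equal weight per cluster, which takes only clusters with at least 50 cells in both libraries and here leaves cluster 6 alone. Over the classes other than macrophage-like cells 71 values stayed within counting error and 3 moved.

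Counts of genes 2-fold apart followed the floor and the fold by construction. For Macrophage-like gene ratios the main 45 became 125 (61 higher, 64 lower) at a floor of 10 CPM, 466 (132, 334) with no floor, 20 (15, 5) at 200 CPM, 205 (117, 88) at 1.5-fold, 10 (8, 2) at 3-fold and 23 (17, 6) with equal weight per cluster. For Progenitor-like gene ratios the main 86 became 229 (72, 157), 985 (167, 818), 32 (23, 9), 256 (122, 134), 23 (8, 15) and 29 (5, 24) in the same order. For T-like gene ratios the main 139 became 625 (123, 502), 1031 (225, 806), 31 (9, 22), 305 (158, 147) and 62 (9, 53) in the same order to 3-fold, and 44 (29, 15) with free RNA subtracted.

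Of the values of named genes, 149 moved in macrophage-like, 108 in progenitor-like and 65 in T-like cells, against 137, 146 and 208 that did not. Reversed were 2 in T-like cells, Hist1h2ae at -0.065 (1.77) and Hist1h1b at -1.18 (main 1.73), both with equal weight per cluster.

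A list counts as reversed when its main median lay outside its random range and its sign changed. Lists mostly from free RNA are left out unless named. Macrophage-like list medians moved as follows. Lipid-associated (-0.60): -0.50 with TMM, -0.49 with median-of-ratios, -0.81 with libraries alone, -0.19 with equal weight. Resident (0.53): 0.65 with median-of-ratios, 0.37 with per-cell CPM, 0.15 with libraries alone, 0.051 with equal weight. Inflammatory (0.79): 0.89 with TMM, 0.90 with median-of-ratios, 0.65 with per-cell CPM, 0.68 with equal weight, 0.89 with no floor. Interferon (0.60): 0.72 with median-of-ratios, 0.39 with equal weight, 0.45 with no floor. Alternative activation (0.53): 0.37 with per-cell CPM, 0.38 with libraries alone, 0.18 with equal weight. Reversed were efferocytosis (0.20) at -0.061 with libraries alone and immediate early genes (0.14) at -0.19 with equal weight.

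By the same rule, the inflammatory list (1.26) reversed in progenitor-like cells to -0.57 with no floor, and cholesterol to -0.060 with no floor. The adipogenic list (0.24) reversed there to -0.056 with equal weight, -0.16 at a floor of 50 CPM and -0.083 with no floor. With no floor a list gains members near 0 counts. By the same rule, the T-like lists that reversed were cholesterol at 0.066 with free RNA subtracted and proliferation (0.83) at -0.46 with equal weight. Equal weight leaves out the cycling cluster. T-like glycolysis and fatty acid oxidation also changed sign, from medians inside their random range. Also in T-like cells, the interferon list (0.44) was 0.17 with equal weight. With free RNA subtracted, the effector and exhaustion list (0.44) was 0.14 and the regulatory T and type 2 cell list (0.63) 0.31. Of T-like lists mostly from free RNA, subtraction turned the inflammatory (-0.44) to 0.13, lysosome (-1.17) to 0.16 and NRF2 lists (-0.50) to 0.085, each on 7 remaining members, and alternative activation (-0.66) to 0.19 on 2. A list with no member left, such as MHC class II genes in T-like cells, gave no value.

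At resolution 0.25 the lipid-associated subcluster (-1.91) was at -0.32 (29.2% against 36.4%) and the resident subcluster (-1.25) reversed to 0.20. The correlation of progenitor-like with macrophage-like ratios (0.491) was 0.406 at a floor of 10 CPM, 0.674 at 200 CPM and 0.593 with little free RNA. Depth limits detection cell by cell, with a kept median of 8257 UMIs in the knockout and 3122.5 in the wild-type library, where the shallow mixed barcodes are counted in.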

Other observations

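B-like, monocyte-like, dendritic-like, natural killer-like and blood endothelial-like cells held further differences, given here for single genes named mostly by the size of their ratio. In B-like cells the joining chain Jchain, a gene of antibody-secreting cells, was at 2199 CPM in the knockout library against 76.4 CPM in the wild type (log2 4.85), with Slpi at 115 against 6.88 CPM (4.06) and Stat4 at 104 against 25.5 CPM (2.04). In cluster 9 alone, the only B-like cluster with at least 50 cells in both libraries, the ratios were 3.79 for Jchain, 3.70 for Slpi and 1.15 for Stat4. Jchain is among the leading genes of B-like cluster 9 (384 knockout and 476 wild-type cells). Lower were Mgmt (11.02 against 272 CPM, -4.63, and -1.35 in cluster 9) and Krt8 (11.02 against 94.8 CPM, and -1.55 in cluster 9); Mgmt is among the leading genes of B-like cluster 21 (23 and 234 cells). Conventional dendritic-like cells had Jchain at 366 against 3 UMIs (6.72, 5.16 to 9.001), the chemokine Cxcl9 at 106 against 28.6 CPM (1.89) and Ccnd2 at 135 against 53.9 CPM (1.33).

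Monocyte-like cells had higher Il1a (83.6 against 25.5 CPM, 1.71), Cxcl1 (1.64) and the growth factor Areg (166 against 63.5 CPM, 1.38) in the knockout library. Their lowest genes, Col3a1, Lum and Mgp, were an estimated 91.2% to 109% free RNA. Col3a1 and Lum are themselves markers that help set this estimate. Natural killer-like cells had higher Itga1 (78.4 against 31.2 CPM, 1.33), Spry2 (315 against 133 CPM, 1.25) and Gimap1os (1.41). Blood endothelial-like cells had higher Nlrp3 (128 against 21.0 CPM, 2.61), Il1b (467 against 77.1 CPM, 2.60) and Ccl7 (257 against 45.3 CPM), and with them the myeloid gene Lyz2 (2879 against 1030 CPM, 1.48); Hp was lower (13.7 against 88.9 CPM, -2.70).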
